A study of Rattus norvegicus with 20 samples.

How the data were processed

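Gene expression was measured on single-colour CodeLink rat whole genome microarrays in RNA from mesenteric arteries of ovariectomised rats, with 1 array per rat and 20 arrays in 6 groups. Replicates are individual rats. The deposited value for each probe and array is a linear intensity after background subtraction and scaling of each array; negative intensities remain in the table, and array medians of the deposited intensities ran from 1.0007 to 1.0612. Slides were read on a GenePix 4000B scanner with GenePix Pro 5.0, per the labels' protocols and the submitters' design text, which also name the CodeLink Expression Analysis software, Acuity 3.1 and GeneSpring 7.1. Which of these programs made the values, how the background was estimated, and the version of the CodeLink software are not given in the sources used here. The array medians spanned 0.08 on the log2 scale, under the limit of 0.2 that had been set for treating the values as already normalised, so no between-array normalisation beyond median centring was applied.

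The table held 35129 probes, of which 16865 carry 1 gene symbol, 165 carry several and 18099 carry none in the probe annotation supplied with the platform. An Entrez identifier was matched for 16836 probes, 1 symbol was updated, and 12199 distinct symbols remained. Neither the table nor the probe annotation gives genome positions, and none is printed. Values at or below 0 were set to 0, an offset of 0.103 (0.1 times the median) was added, and the sum was log2-transformed and centred on the median of each array. The offset understates the change of genes with low intensity. After 40 probes missing in more than 1 array of a group and the lowest 30% of the remaining 35089 probes by mean were left out, 24562 probes were tested, 13324 of them with 1 symbol, for 10191 genes.

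One linear model with a mean for each of the 6 groups was fitted over all 20 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend in mean intensity. Comparisons were contrasts of these means: each compound against vehicle, the compounds within a class against each other, the mean of the estrogens and the mean of the selective estrogen receptor modulators (SERMs) against vehicle and against each other, and an F-test of any difference from vehicle. P-values were adjusted by the Benjamini-Hochberg method, and a probe is said to have passed, risen or fallen where limma's adjusted p was under 0.05. For gene groups, 30 lists of pathway and cell type genes were tested with limma's camera at a preset correlation of 0.01, and again with the correlation estimated per list, using the brightest complete probe of each gene; 847 of the 1013 listed genes were matched. For a gene group that passed with all arrays, its median log2 change and the adjusted p at both correlations are given, and for most the number of members that passed; a count over the list alone is adjusted over only the genes of that list, and an unadjusted count is at an unadjusted p under 0.05. Differences in mean list score between compounds are given with 95% confidence intervals (CI) for the matrix, cell cycle, fatty acid and smooth muscle lists; for other lists that passed it is stated where the interval includes 0.

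The groups, comparisons, gene lists, filters, tests and a set of alternatives were chosen before the data were examined. Genes were named by a rule fixed then: for each comparison with vehicle up to 8 highest and 8 lowest probes with 1 symbol that passed and whose groups did not overlap, up to 4 members of each list that passed (2 for cell type lists), and 12 fixed genes; comparisons between compounds and of class means used 5 and 2 in place of 8 and 4. The probe of a gene can differ between comparisons, as for Me1, Elovl6, Cyp2e1, Fmo2 and Col1a1. Ednra, also in the fixed set, was not matched to a tested probe and is not analysed here. Some results that this rule selects are not reported here. The scripts were tested on simulated data. For ethinyl estradiol versus vehicle, 0, 30, 39 and 45 of 50 probes changed by 0.5, 1, 1.5 and 2 (log2) were recovered. False calls were 12 of 24362 unchanged probes. For tamoxifen the numbers were 4, 32, 41, 45 and 7. Other splits of the real arrays called up to 405 and 19.

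Alternatives set beforehand were quantile normalisation, no centring, a larger and a smaller offset, no filter and a stricter filter on dim probes, no variance trend, array weights, a fit of only the compared groups, replicate number as a block, an estimated correlation for the lists, the mean over all probes of a gene, and leaving out each array in turn. Alternatives chosen after seeing the data were a block for the array set described in the results, leaving out 1 or 2 outlying arrays, both choices together, control arrays from the same array set, and leaving out a class of regularly spaced unnamed probes. Because vehicle arrays are shared by the 5 comparisons with vehicle, correlations between their changes are given with the value from simulated data without effects and with the value from separate vehicle arrays for each compound. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.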

Results

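Rats were ovariectomised at 4 weeks of age, left to recover for 2 weeks and gavaged daily for 3 weeks, so that tissue was taken at 9 weeks. The groups were vehicle, a cyclodextrin solution (4 arrays), ethinyl estradiol (3), estradiol benzoate (3) and equilin (3), each at 0.15 mg/kg per day, and tamoxifen (4) and raloxifene (3), each at 3 mg/kg per day; the design text gives 3 to 4 rats per group and 3 arrays for each treatment. The mesenteric artery, which supplies the gut and contributes to vascular resistance, was profiled on 1 array per rat. The number of arrays limits the precision of every value. The design asks how gene expression in this artery responds to estrogens and to SERMs, drugs that bind estrogen receptors and act as agonists or antagonists depending on the tissue.

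The arrays fell into 2 sets that the labels do not name. Set A, with deposited medians of 1.0408 or more, held vehicle array 1 and all 9 estrogen arrays; set B, with medians of 1.015 or less, held vehicle arrays 2, 3 and 4 and all 7 SERM arrays. A class of 384 unnamed probes at regular steps of the probe numbering separated the sets: the median of these probes lay between 0.86 and 2.02 on the centred log2 scale in set A and at -1.20 or lower in set B. Their identity is not given in the sources used here; the design text says that bacterial control RNAs were added to the samples without naming the probes that measure them. Of the 384, 336 were tested, and they are called the regularly spaced probes. Each comparison with vehicle is therefore also given with the array set as a block, which sets each estrogen against vehicle array 1 alone and each SERM against vehicle arrays 2, 3 and 4. The lone control of the estrogens there is assumed to vary like the arrays of the other groups, so p-values from that fit rest on this assumption. Raloxifene array 3 stood apart from the rest, with a mean correlation of 0.841 with the other arrays. Relative to vehicle, the median probe moved by -0.17 under equilin, -0.12 under estradiol benzoate and -0.13 for the estrogen mean; with quantile normalisation these medians were -0.01, -0.00 and -0.02. List medians for these 3 comparisons are given relative to that shift, and changes of single genes are given as fitted.

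**Figure D1:**
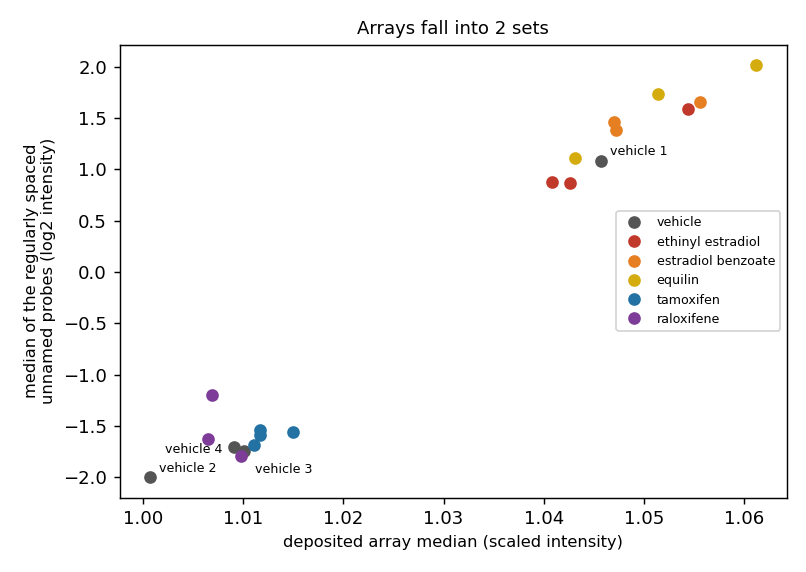
Each point is 1 of the 20 arrays; the horizontal axis is its deposited median intensity and the vertical axis the median centred log2 value of the regularly spaced unnamed probes, with colour for the treatment group. Vehicle array 1 lies at 1.08 on the vertical axis with the estrogen arrays, and the other vehicle arrays lie at -1.71 or lower with the SERM arrays.

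Ethinyl estradiol, an orally active estradiol with an added ethynyl group, raised enzymes that make fatty acids. Changes are log2 values with the standard error of the fit. Me1, the malic enzyme that supplies NADPH for lipid synthesis, averaged 6.29 ± 0.42 (SD, n = 3) against 4.21 ± 0.20 (SD, n = 4) under vehicle, a change of 2.08 ± 0.24 with limma's adjusted p = 0.000559. Elovl6, a fatty acid elongase, rose by 2.18 ± 0.35, Scd, the stearoyl-CoA desaturase, by 1.96 ± 0.33, Aacs, an acetoacetyl-CoA synthetase, by 1.54 ± 0.30 and Thrsp, a lipogenic regulator, by 1.18 ± 0.18. In the fatty acid and triglyceride synthesis list 7 of 24 genes rose (9 higher and 1 lower over the list alone), and the list passed (median 0.50, adjusted p = 2.29e-09, 0.0383 estimated; the last value, here and below, is the adjusted p with an estimated correlation). Cyp2e1, a cytochrome P450 of xenobiotic metabolism, rose by 2.56 ± 0.54, Cbr1, a carbonyl reductase, by 1.85 ± 0.24, Spink5, a serine protease inhibitor, by 2.05 ± 0.43 and Ubd, a ubiquitin-like modifier, by 2.22 ± 0.52.

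Genes of the extracellular matrix and of dividing cells fell under ethinyl estradiol. Col1a1, a fibrillar collagen chain, changed by -1.53 ± 0.26, Postn, the matrix protein periostin, by -1.27 ± 0.21, Pcolce, an enhancer of procollagen processing, by -1.04 ± 0.18 and Fn1, fibronectin, by -1.04 ± 0.19. In the extracellular matrix list 8 of 50 genes fell (15 lower over the list alone), and the list passed (median -0.50, adjusted p = 2.48e-06, 0.0383 estimated). Top2a, a topoisomerase of dividing cells, averaged -0.42 ± 0.30 (SD, n = 3) against 1.42 ± 0.21 (SD, n = 4) under vehicle, a change of -1.83 ± 0.20. Nusap1, a mitotic spindle gene, changed by -1.42 ± 0.20, Pbk, a mitotic kinase, by -1.74 ± 0.30 and Ccna2, a cyclin, by -1.01 ± 0.20. In the cell cycle list 8 of 38 genes fell (1 higher and 17 lower over the list alone), and the list passed (median -0.48, adjusted p = 3.73e-07, 0.0911 estimated). Among other genes, Sfrp4, a secreted Wnt antagonist, changed by -2.28 ± 0.34, Apln, the vasoactive peptide apelin, by -2.20 ± 0.43 (-1.30 without ethinyl estradiol array 3) and Cpz, a carboxypeptidase, by -1.99 ± 0.18. Cish, a suppressor of cytokine signalling, changed by -1.95 ± 0.42, A2m, a protease inhibitor, by -1.74 ± 0.33 and Hsd11b2, which inactivates glucocorticoids, by -1.68 ± 0.23. Other Cish probes read 0.38 and -0.07 and another Fn1 probe -0.01.

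Markers of mast cells and fibroblasts were lower. Hdc, which makes histamine, changed by -0.99 ± 0.19 and Mcpt10, a mast cell protease, by -0.94 ± 0.20. In the mast cell list 3 of 16 genes fell (6 lower over the list alone), and the list passed (median -0.48, adjusted p = 0.000907, 0.0383 estimated). Col14a1, a fibroblast collagen, changed by -0.81 ± 0.16. In the fibroblast and progenitor list 1 of 19 genes fell (6 lower over the list alone) (median -0.55, adjusted p = 0.00156, 0.0911 estimated). The macrophage and dendritic cell list also fell (median -0.49, adjusted p = 0.00322, 0.204 estimated), where 1 of 27 genes fell (4 lower over the list alone). Its member Clec9a, a dendritic cell receptor, changed by -1.02 ± 0.21. The T and B lymphocyte list fell (median -0.47, adjusted p = 0.00525, 0.353 estimated), although 0 of 18 genes passed by limma (0 over the list alone, 6 lower unadjusted).

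Smooth muscle contractile genes passed upward as a list (median 0.14, adjusted p = 0.0015, 0.105 estimated, score 95% CI -0.05 to 0.34). Of 30 genes 1 rose and 1 fell, also over the list alone. Lmod1, a leiomodin of smooth muscle, rose by 0.81 ± 0.16, while Mylk, myosin light chain kinase, at 1.46 ± 0.55 (another probe 0.07) and Pln, phospholamban, at 0.42 ± 0.21 did not pass. The sterol synthesis list passed upward (median 0.17, adjusted p = 0.00239, 0.349 estimated), at scores of -0.17 to 0.49 (vehicle -0.18 to 0.20). Of 21 genes 0 passed, also over the list alone (3 higher unadjusted). In the immediate early and heat shock list, which passed upward (median 0.10, adjusted p = 0.0046, 0.322 estimated), 1 of 30 genes rose (1 higher over the list alone), the small heat shock gene Hspb1 at 0.96 ± 0.20. In the interferon response list, which passed upward (median 0.01, adjusted p = 0.0208, 0.333 estimated), 1 of 41 genes fell (1 higher and 1 lower over the list alone). The pancreatic acinar list, which marks an organ next to the artery, passed upward (median 0.38, adjusted p = 0.0315, 0.673 estimated). Of its 19 genes 0 passed (0 unadjusted). Its score relative to vehicle was -1.59, -1.89 and 4.66 in the 3 arrays, and without ethinyl estradiol array 3 the list passed downward (median -1.80, adjusted p = 6.18e-05).

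In all, 295 probes passed for ethinyl estradiol (133 higher and 162 lower), of which 154 had 1 symbol and 74 were regularly spaced. With the regularly spaced probes left out, 164 passed and Ubd did not. With the array set as a block, 134 passed (120 higher and 14 lower), 30 of them among the 295. Of the named genes, Me1, Scd, Thrsp, Cbr1, Cpz, Top2a, Nusap1, Col1a1, Postn and Fn1 passed there. Of the vehicle arrays, array 1, the lone control there, read lowest for Me1, Scd (4.06 against 5.54 to 6.16) and Thrsp and highest for Col1a1, Postn and Fn1, which enlarges these changes. With the block the matrix list median was -0.58 (adjusted p = 1.22e-10, 0.00213 estimated), the fatty acid list median 0.70 (adjusted p = 1.28e-09, 0.0282 estimated) and the pancreatic list median -1.73 (adjusted p = 0.0285, 0.805 estimated), and the smooth muscle, interferon, immediate early and T and B lymphocyte lists did not pass. Leaving out 1 array at a time gave 74 probes (without ethinyl estradiol array 1) to 575 (without vehicle array 1). Leaving out raloxifene array 3, which enters this comparison through the variance alone, gave 743, and there 0 lists passed with an estimated correlation (matrix and fatty acid 0.0896, mast cell 0.108).

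Estradiol benzoate, the benzoate ester of estradiol at the same dose, gave few changes in named genes. Dusp9, a phosphatase that inactivates MAP kinases, stood at 1.15 ± 0.19, Hsd17b2, which oxidises estradiol to estrone, at 0.90 ± 0.19 and Inhbb, an activin and inhibin subunit, at 0.86 ± 0.18. The transcription factor gene Tp63 was also higher. Lower values were seen for Myocd, a coactivator of smooth muscle genes, at -1.31 ± 0.28, Ada, adenosine deaminase, at -1.12 ± 0.20, Crem, a cyclic AMP-responsive factor, at -0.90 ± 0.20, Unc45a, a myosin chaperone, at -1.34 ± 0.26, Rfx2 at -1.23 ± 0.26, Mib2 at -1.04 ± 0.23 and Sh3bp5l at -1.49 ± 0.26. Other probes of Ada and Unc45a read -0.53 and -0.57. Dusp9 averaged -0.75 ± 0.08 (SD, n = 3) against -1.90 ± 0.40 (SD, n = 4) under vehicle. Each of these 11 genes passed only when the regularly spaced probes were among those tested (adjusted p 0.0435 to 0.0472); with those probes left out, their adjusted p ran from 0.115 to 0.356. In all 172 probes passed (156 higher and 16 lower), 151 of them regularly spaced and 11 with 1 symbol; with the regularly spaced probes left out, 0 passed by limma, against 1565 at an unadjusted p under 0.05.

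As lists, smooth muscle genes fell (median -0.18, adjusted p = 0.043, 0.521 estimated), where 1 of 30 genes fell (2 lower over the list alone). Cell cycle genes fell (median -0.17, adjusted p = 0.0325, 0.558 estimated), although 0 of 38 genes passed by limma (3 lower over the list alone, 1 higher and 12 lower unadjusted). The steroid receptor and estrogen-responsive list passed upward (median 0.08, adjusted p = 0.043, 0.0923 estimated), where 1 of 30 genes rose (1 higher and 2 lower over the list alone). Its median as fitted was -0.04 and its mean -0.03, opposite in sign to the test. Of the cell type lists, lymphatic and venous endothelium rose (median 0.33, adjusted p = 0.0343, 0.0923 estimated). Enteric smooth muscle and interstitial cell genes rose (median 0.33, adjusted p = 0.0073, 0.0923 estimated). Pancreatic genes fell (median -1.51, adjusted p = 0.043, 0.78 estimated). In each of these 3 cell type lists 0 genes passed by limma and 0 had an unadjusted p under 0.05. The matrix list did not pass (median -0.12, adjusted p = 0.0768).

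The fit with the array set as a block gave 100 probes, 3 of them among the 172, with Tp63 and Hsd17b2 among the named genes. Both rest on low readings of vehicle array 1, the lone control there: -2.02 against -1.33 to -1.12 and -2.22 against -1.47 to -1.35 in the other vehicle arrays. There 12 lists passed, among them matrix (median -0.45 as fitted, adjusted p = 3.02e-05, 0.0607 estimated) but not steroid, cell cycle and enteric, and 0 with an estimated correlation. Without single arrays the count ran from 0 (without vehicle array 3) to 357 (without vehicle array 1).

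Equilin, an equine estrogen with an extra ring double bond and a ketone in place of the 17-hydroxyl, raised lipid synthesis genes and lowered matrix, cell cycle and smooth muscle genes. By another probe than above, Me1 averaged 3.61 ± 0.57 (SD, n = 3) against 1.79 ± 0.28 (SD, n = 4) under vehicle, a change of 1.82 ± 0.26 with limma's adjusted p = 0.00806. Elovl6, also by another probe, rose by 1.69 ± 0.37, Scd by 1.46 ± 0.33, Acaca, acetyl-CoA carboxylase, by 1.40 ± 0.31, Pc, pyruvate carboxylase, by 1.66 ± 0.31 (other probes 0.30 to 1.55) and Thrsp by 0.81 ± 0.18. In the fatty acid list 5 of 24 genes rose and 1 fell (7 higher and 1 lower over the list alone), and the list passed (median 0.53, adjusted p = 1.44e-08, 0.073 estimated). Spink5 rose by 1.80 ± 0.43, Cbr1 by 1.56 ± 0.24 and Cyp2e1 by 2.01 ± 0.54, with adjusted p of 0.00806 to 0.0468 for the 3 genes.

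Cell cycle, matrix and smooth muscle genes were lower under equilin. Top2a averaged 0.04 ± 0.17 (SD, n = 3) against 1.42 ± 0.21 (SD, n = 4) under vehicle, a change of -1.37 ± 0.20. Nusap1 changed by -1.13 ± 0.20, Cks2, a cyclin-dependent kinase subunit, by -1.18 ± 0.22 and Racgap1 by -0.80 ± 0.17. In the cell cycle list 12 of 38 genes fell (1 higher and 17 lower over the list alone), and the list passed (median -0.36, adjusted p = 0.00224, 0.298 estimated). Tnc, tenascin C, changed by -1.76 ± 0.34, Col5a2 by -1.12 ± 0.23, Col18a1 by -1.01 ± 0.19 and Pcolce by -0.94 ± 0.18. In the matrix list 8 of 50 genes fell (17 lower over the list alone), and the list passed (median -0.41, adjusted p = 0.00121, 0.073 estimated). Pln changed by -0.89 ± 0.21, Myocd by -1.10 ± 0.28, Synpo2 by -1.11 ± 0.29 and Tpm1, a tropomyosin, by -0.52 ± 0.14. In the smooth muscle list 5 of 30 genes fell (10 lower over the list alone), and the list passed (median -0.30, adjusted p = 0.0256, 0.268 estimated). Other falls were Alpl, alkaline phosphatase, at -1.87 ± 0.29, C1qtnf12 at -1.78 ± 0.28, Sfrp4 at -1.75 ± 0.34, Itga1, an integrin chain, at -1.79 ± 0.44, Tekt3 at -1.99 ± 0.49 and the clock gene Per2 at -1.99 ± 0.52, which without equilin array 1 stood at -0.94 and did not pass. Cish stood at -2.32 ± 0.42, and its other probes read 0.72 and 0.15.

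The mast cell and macrophage lists did not pass (adjusted p = 0.228 for each), although their scores were lower than under vehicle, with differences of -0.37 (95% CI -0.53 to -0.21) and -0.42 (95% CI -0.65 to -0.19). The steroid receptor and estrogen-responsive list passed upward (median 0.22, adjusted p = 0.0266, 0.073 estimated), where 1 of 30 genes rose and 1 fell (2 higher and 2 lower over the list alone). Its median as fitted was 0.06 and its mean -0.04. Oxtr, the oxytocin receptor, rose by 0.98 ± 0.24, and Pgr, the progesterone receptor, stood at 0.44 ± 0.16 without passing. Adipocyte genes, which mark the fat around the artery, rose as a list (median 0.38, adjusted p = 2.94e-06, 0.062 estimated), although 0 of 22 genes passed by limma (0 over the list alone, 4 higher and 1 lower unadjusted). Lymphatic and venous endothelial genes rose (median 0.38, adjusted p = 0.0458, 0.113 estimated). Enteric smooth muscle and interstitial cell genes rose (median 0.51, adjusted p = 0.00755, 0.0948 estimated). Erythroid genes passed upward (median 0.38, adjusted p = 0.0238, 0.312 estimated). In order, 0 of 9, 6 and 9 genes passed, also over the list alone. Unadjusted counts were 1 lower, 2 higher, and 1 higher and 1 lower. Erythroid scores (-0.03 to 0.21) lay within those of vehicle (-0.28 to 0.31).

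In all, 906 probes passed for equilin (430 higher and 476 lower), 377 with 1 symbol and 298 regularly spaced. With quantile normalisation 522 were higher and 213 lower, and with no centring 468 and 317. With the regularly spaced probes left out, 279 passed (72 higher and 207 lower), and Cyp2e1, Oxtr, Tekt3, Per2, Itga1, Myocd, Tpm1 and Synpo2 did not. The array set block left 159 (151 higher and 8 lower), 38 of them among the 906. Of the named genes, Me1 and Scd passed, both again lowest in vehicle array 1. There the fitted list medians were -0.57 for matrix (adjusted p = 1.66e-08, 0.00703 estimated), 0.60 for fatty acid (adjusted p = 1.86e-09, 0.0536 estimated) and -0.39 for cell cycle (adjusted p = 0.0246, 0.322 estimated), while the steroid and enteric lists did not pass. Leaving out 1 array at a time gave 0 probes (without equilin array 2) to 1429 (without vehicle array 2), and leaving out raloxifene array 3 gave 3069.

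Tamoxifen, a triphenylethylene SERM, lowered cell cycle and matrix genes. Top2a averaged -0.29 ± 0.26 (SD, n = 4) against 1.42 ± 0.21 (SD, n = 4) under vehicle, a change of -1.71 ± 0.19 with limma's adjusted p = 0.000323. Mki67, a proliferation marker, was lower (adjusted p = 0.0261). Cks2 changed by -1.38 ± 0.21, Nusap1 by -1.23 ± 0.19 and Ccna2 by -1.13 ± 0.19. In the cell cycle list 8 of 38 genes fell (13 lower over the list alone), and the list passed (median -0.33, adjusted p = 1.66e-09, 0.0855 estimated). Tnc changed by -1.68 ± 0.31, Col1a1 by -1.64 ± 0.24, Postn by -1.11 ± 0.20 and Fn1 by -0.98 ± 0.17. In the matrix list 4 of 50 genes fell (14 lower over the list alone), and the list passed (median -0.34, adjusted p = 1.12e-09, 0.00443 estimated). Hsd11b2 changed by -1.49 ± 0.22, Cpz by -1.48 ± 0.17, Sfrp4 by -1.60 ± 0.31 and Cish by -1.96 ± 0.39, other probes of which read 0.17 and -0.38. Cyp2e1 rose by 3.68 ± 0.55, Bcl6, a transcriptional repressor, by 1.75 ± 0.26 (another probe 0.92), Ntsr1, a neurotensin receptor, by 1.72 ± 0.18 and Dusp9 by 0.94 ± 0.18.

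Smooth muscle genes fell as a list under tamoxifen (median -0.28, adjusted p = 0.000734, 0.149 estimated), although 0 of 30 genes passed by limma (0 over the list alone, 5 lower unadjusted). The fibroblast and progenitor list fell (median -0.20, adjusted p = 0.0311, 0.22 estimated), although 0 of 19 genes passed by limma (0 over the list alone, 4 lower unadjusted). The T and B lymphocyte list fell (median -0.29, adjusted p = 0.0153, 0.51 estimated), although 0 of 18 genes passed by limma (2 lower over the list alone, 2 lower unadjusted). The adipocyte list rose (median 0.11, adjusted p = 0.00803, 0.179 estimated), although 0 of 22 genes passed by limma (0 over the list alone, 3 higher unadjusted). The pancreatic list rose (median 1.53, adjusted p = 6.71e-05, 0.574 estimated), although 0 of 19 genes passed by limma (0 over the list alone, 0 unadjusted). Vehicle arrays scored 1.94, -0.42, -2.02 and 0.50 on the pancreatic list and tamoxifen arrays 1.71, 2.49, 1.19 and 0.15.

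In all, 55 probes passed for tamoxifen (9 higher and 46 lower), 40 of them with 1 symbol. With quantile normalisation 14 were higher and 35 lower. Under the array set block 26 passed, 25 of them among the 55. Of the named genes that passed, Cish (-2.15 ± 0.42), Sfrp4 (-1.57 ± 0.34), Fn1 (-0.90 ± 0.18) and Postn (-1.01 ± 0.21) did not pass with the block, at larger standard errors. There the matrix list median was -0.31 (estimated adjusted p = 0.00891) and that of the cell cycle list -0.44 (estimated adjusted p = 0.0266), and the fibroblast list did not pass. With single arrays left out the fit gave 18 probes (without tamoxifen array 1) to 120 (without tamoxifen array 3), and leaving out raloxifene array 3 gave 166.

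Raloxifene, a benzothiophene SERM given at the tamoxifen dose, lowered Armc5 in each of the 3 fits given here. Armc5, an armadillo repeat gene, averaged 1.04 ± 0.60 (SD, n = 3) against 3.40 ± 0.31 (SD, n = 4) under vehicle, a change of -2.36 ± 0.30 with limma's adjusted p = 0.00643; its other probe read -0.82 and did not pass. The named probe also passed without raloxifene array 3 (adjusted p = 0.0188) and with the array set as a block (adjusted p = 0.0139). The other named genes passed with all arrays but neither without raloxifene array 3 nor with the block. Of these, the growth factor gene Igf1 stood at -2.23 ± 0.53, the transcription factor gene Tcf4 at -1.93 ± 0.46, Cdca4 at -1.80 ± 0.40, Nfat5, an osmotic stress factor, at -1.72 ± 0.43, Lmf2 at -1.72 ± 0.41, Sfrp4 at -1.69 ± 0.34 and Brd3 at -1.68 ± 0.43. Higher values were those of Rassf3 at 1.99 ± 0.36, the sulfatase gene Arsk at 1.62 ± 0.26, Baz2b at 1.57 ± 0.29, Wdr44 at 1.55 ± 0.29, Zfp667 at 1.49 ± 0.34, Gorab at 1.49 ± 0.31 and Acadsb at 1.43 ± 0.35. Without raloxifene array 3, Igf1 stood at -1.24, Tcf4 at -0.97, Cdca4 at -1.04, Nfat5 at -0.90, Lmf2 at -0.90, Sfrp4 at -1.11, Brd3 at -0.98 and Gorab at 0.98. Other probes read -1.06 for Gorab, 0.36 for Rassf3, 0.21 for Arsk, 0.37 for Zfp667, 0.18 for Acadsb and 0.19, 0.29, -1.11 and 0.03 for Nfat5. By camera 0 gene lists passed (3 unadjusted). The matrix list stood at -0.33 (adjusted p = 0.125) and the cell cycle list at -0.13 (adjusted p = 0.733). Cell cycle scores were -0.29, -0.22 and, in array 3, -0.002 (vehicle -0.14 to 0.06).

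In all, 502 probes passed for raloxifene (178 higher and 324 lower), 289 with 1 symbol, and with quantile normalisation 271 were higher and 207 lower. Without raloxifene array 3, 14 passed, 12 of them among the 502, and the matrix list passed with a median of -0.30 (adjusted p = 0.00335), though not with an estimated correlation (adjusted p = 0.82). The array set block left 5. Without single arrays the count ran from 5 probes (without vehicle array 1) to 3774 (without raloxifene array 2).

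**Figure D2:**
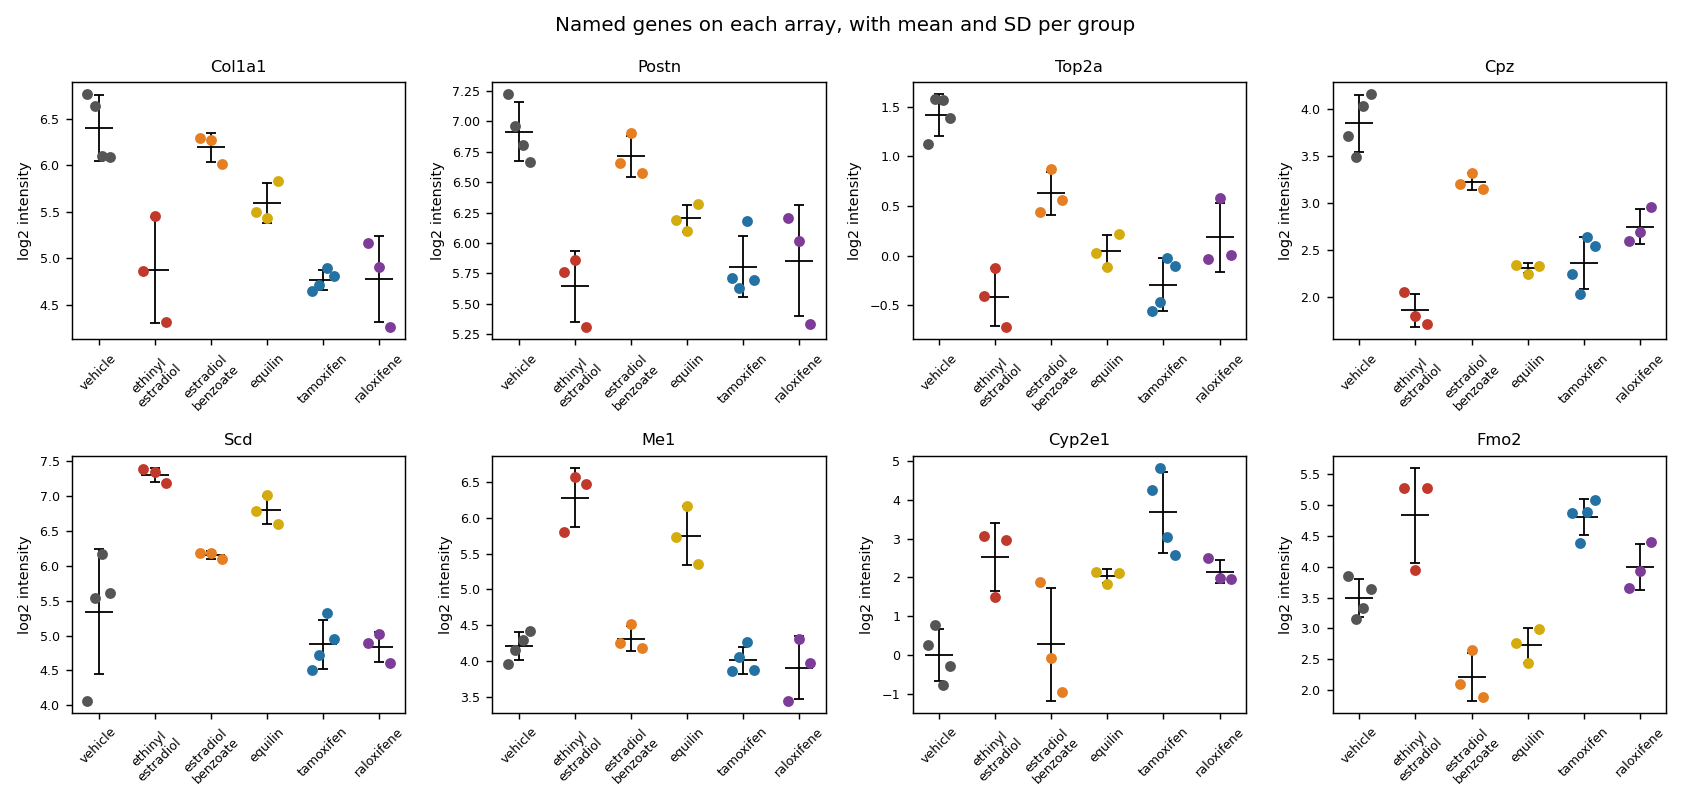
Centred log2 intensity of 8 named genes by treatment group; each point is 1 array and bars are the mean with its SD. Col1a1, Postn, Top2a, Cpz and Cyp2e1 are shown by the probe named under tamoxifen, Me1 and Scd by the probe named under ethinyl estradiol and Fmo2 by the probe named for ethinyl estradiol against estradiol benzoate.

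**Figure D3:**
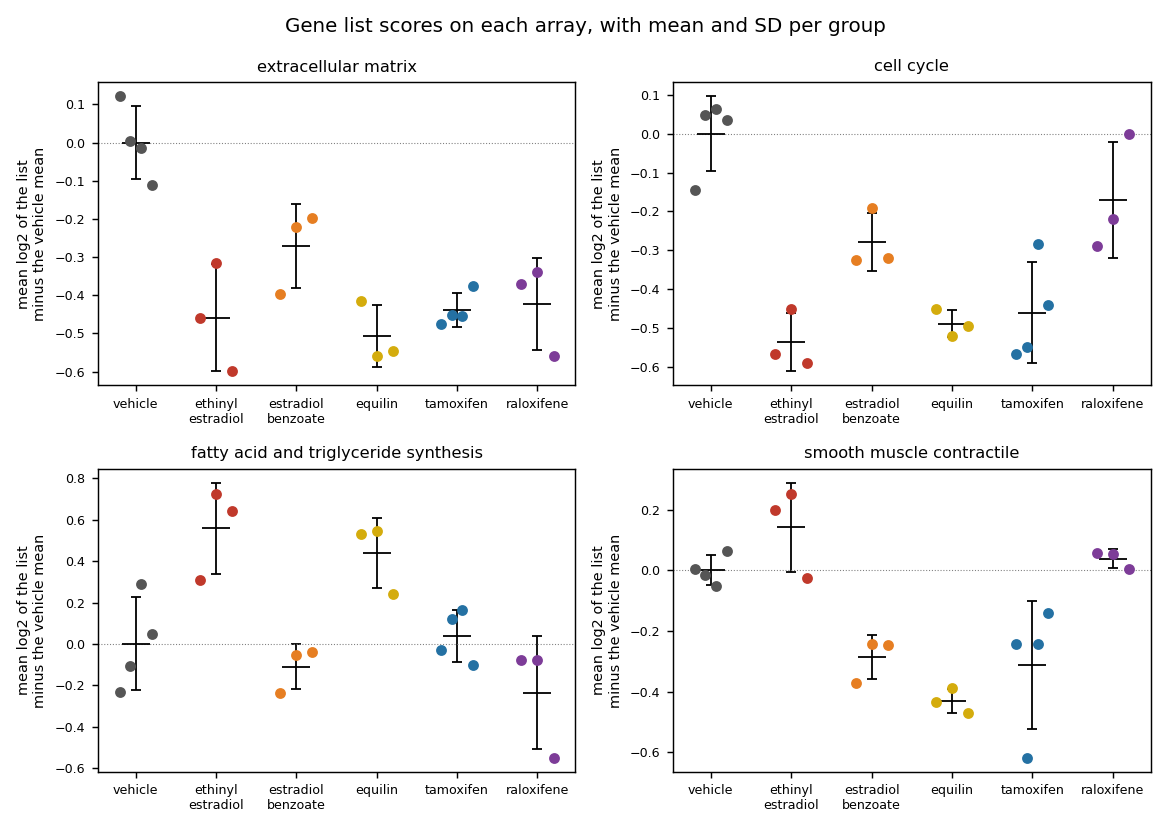
Mean log2 value of each gene list relative to the vehicle mean (vertical axis) by treatment group; each point is 1 array and bars are the mean with its SD. Every treated array lies at -0.20 or lower on the extracellular matrix list, and the lowest vehicle array at -0.11.

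The mean of the estrogens against vehicle averages the class, so a change under 2 of the 3 compounds can carry it: under estradiol benzoate Me1 stood at 0.11 and the fatty acid score at -0.11. Dusp9 rose by 1.02 ± 0.15, Tp63 by 0.96 ± 0.17, Spock1, a proteoglycan, by 0.94 ± 0.17, Hsd17b2 by 0.88 ± 0.15 and Pak3 by 0.70 ± 0.14 (another probe 0.16). Cpz changed by -1.38 ± 0.14, Top2a by -1.33 ± 0.16, Alpl by -1.43 ± 0.23, Sfrp4 by -1.45 ± 0.26, Tekt3 by -1.73 ± 0.39 and Nusap1 by -1.10 ± 0.16. In the matrix list 10 of 50 genes fell (15 lower over the list alone) (median -0.32, adjusted p = 3.58e-05, 0.0844 estimated). In the cell cycle list 12 of 38 genes fell (1 higher and 19 lower over the list alone) (median -0.33, adjusted p = 3.58e-05, 0.131 estimated). In the fatty acid list 5 of 24 genes rose (7 higher and 1 lower over the list alone) (median 0.43, adjusted p = 2.63e-08, 0.0857 estimated), with Me1 at 1.25 ± 0.19 and Scd at 1.41 ± 0.26. In the mast cell list 3 of 16 genes fell (5 lower over the list alone) (median -0.24, adjusted p = 0.0307, 0.113 estimated), with Hdc at -0.74 ± 0.15 and Cpa3, a mast cell protease, at -0.61 ± 0.12. In the macrophage and dendritic cell list 2 of 27 genes fell (2 lower over the list alone) (median -0.18, adjusted p = 0.0347, 0.335 estimated), with Clec9a at -0.71 ± 0.16 and Mpeg1 at -0.60 ± 0.14.

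The steroid list passed upward for the estrogen mean (median 0.13, adjusted p = 0.0482, 0.101 estimated), with a fitted median of 0.01 and a mean of -0.06. The sterol list passed upward too (median 0.17, adjusted p = 0.0347, 0.643 estimated), with a fitted median of 0.04 and a mean of -0.01. Adipocyte (median 0.25, adjusted p = 0.00137, 0.101 estimated), enteric (median 0.35, adjusted p = 0.00338, 0.101 estimated) and erythroid genes (median 0.31, adjusted p = 0.0307, 0.335 estimated) passed upward as lists, in which by limma 0 genes passed, against 3, 2 and 1 at an unadjusted p under 0.05. The adipocyte score differed from vehicle by 0.10 (95% CI -0.10 to 0.30) and the erythroid score by 0.04 (95% CI -0.25 to 0.33), and both intervals include 0. In all, 640 probes passed (418 higher and 222 lower), 317 of them regularly spaced, and with quantile normalisation 468 were higher and 110 lower. With the regularly spaced probes left out 114 passed (34 higher and 80 lower), and Clec9a, Mpeg1 and Tekt3 did not. Under the array set block 167 passed, 28 of them among the 640. Of the named genes, Cpz, Hsd17b2, Me1, Scd, Spock1 and Tp63 passed, and of these all but Cpz read lowest in vehicle array 1 (Spock1 3.14 against 3.87 to 4.16). Without single arrays the count ran from 298 (without vehicle array 3) to 670 (without vehicle array 2), and leaving out raloxifene array 3 gave 1379.

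For the mean of the SERMs, Cyp2e1 rose by 2.91 ± 0.49, Bcl6 by 1.43 ± 0.23 (another probe 0.61), Arsk by 1.37 ± 0.21 (another probe 0.27), Bin2a by 1.35 ± 0.25 and Ntsr1 by 1.24 ± 0.16. Col1a1 changed by -1.63 ± 0.21 with limma's adjusted p = 0.00164. Sfrp4 changed by -1.65 ± 0.28, Mki67 by -1.55 ± 0.25, Top2a by -1.47 ± 0.17, C1qtnf3, an adipokine-like protein, by -1.38 ± 0.21, Postn by -1.09 ± 0.17 and Cks2 by -1.34 ± 0.19. In the matrix list 4 of 50 genes fell (18 lower over the list alone) (median -0.35, adjusted p = 6.89e-05, 0.0746 estimated). In the cell cycle list 6 of 38 genes fell (1 higher and 12 lower over the list alone) (median -0.27, adjusted p = 0.0209, 0.575 estimated). In all, 141 probes passed (47 higher and 94 lower), and with quantile normalisation 72 were higher and 66 lower. The array set block left 33, with Arsk, C1qtnf3, Cks2, Col1a1, Cyp2e1, Mki67, Ntsr1 and Top2a among the named genes. With single arrays left out the fit gave 33 (without vehicle array 1) to 914 (without vehicle array 4), and 262 without raloxifene array 3.

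An F-test of any difference from vehicle passed for 2171 probes, 1556 without the regularly spaced probes, 169 with the array set as a block and 3093 without raloxifene array 3. The 10 named probes with the smallest adjusted p were Me1, Cpz, Ntsr1, Col1a1, Top2a, Fmo2, Mpc1, Cbr1, Atosa and Hspb1, and all of them also passed with each of the first 2 of those changes. Fmo2, a flavin monooxygenase, stood at 1.34 under ethinyl estradiol, -1.28 under estradiol benzoate and -0.77 under equilin (F-test adjusted p = 0.000453). In the same order Mpc1, a mitochondrial pyruvate carrier, stood at 1.17, 0.00 and 0.95 and Atosa at 1.34, -0.46 and 0.27.

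**Figure D4:**
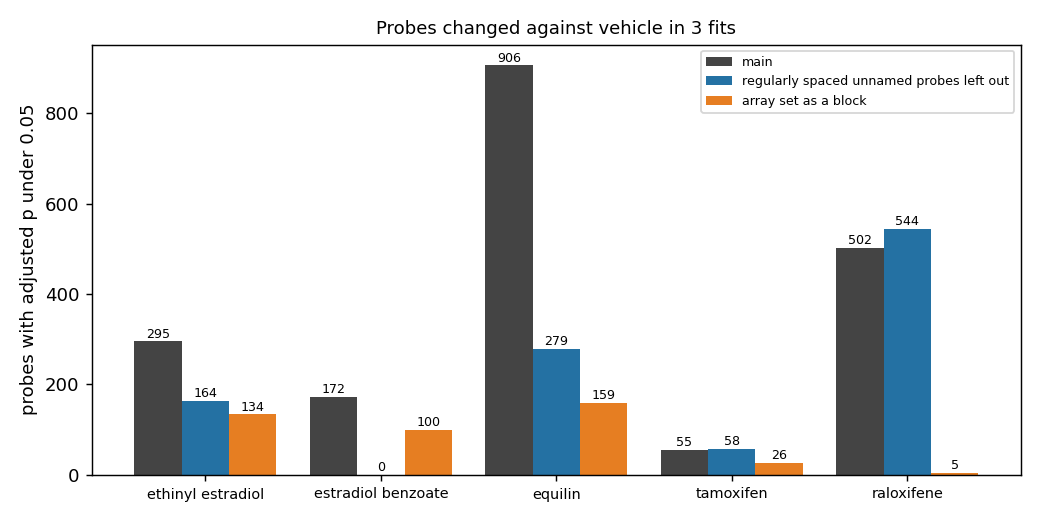
Number of probes with limma's adjusted p under 0.05 (vertical axis) for each comparison in 3 fits: all tested probes, the regularly spaced probes left out, and the array set as a block. For estradiol benzoate the bars are 172, 0 and 100 probes.

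At the shared dose of 0.15 mg/kg, ethinyl estradiol and estradiol benzoate, which differ by the ethynyl group and the ester, differed in lipid, matrix and smooth muscle genes. Fmo2 was higher under ethinyl estradiol by 2.62 ± 0.33, at 4.84 ± 0.77 (SD, n = 3) against 2.21 ± 0.39 (SD, n = 3), with limma's adjusted p = 0.00127. Elovl6 was higher by 2.06 ± 0.37, Me1 by 1.97 ± 0.25, Cbr1 by 1.97 ± 0.26 and Thrsp by 1.08 ± 0.19. Fkbp5, a glucocorticoid-responsive co-chaperone, was higher (adjusted p = 0.039). Hspb1 differed by 1.68 ± 0.21 and Lmod1 by 1.21 ± 0.17, and Myocd was higher (adjusted p = 0.0432). Sfrp4 differed by -1.94 ± 0.36, Hsd11b2 by -1.79 ± 0.25, Cpz by -1.37 ± 0.20, Nnat, neuronatin, by -1.36 ± 0.20, Pola2, a DNA polymerase subunit, by -1.34 ± 0.26, Col1a1 by -1.32 ± 0.27 and Top2a by -1.04 ± 0.22. The fatty acid score differed by 0.67 (95% CI 0.33 to 1.01); in this list 3 of 24 genes were higher (10 higher over the list alone) (median 0.62, adjusted p = 2.14e-07, 0.0661 estimated). The smooth muscle score differed by 0.43 (95% CI 0.22 to 0.64); 2 of 30 genes were higher (4 higher over the list alone) (median 0.45, adjusted p = 9.48e-07, 0.054 estimated). The matrix score differed by -0.19 (95% CI -0.36 to -0.01); 1 of 50 genes were lower (8 lower over the list alone) (median -0.26, adjusted p = 0.0004, 0.0661 estimated). The cell cycle score differed by -0.26 (95% CI -0.44 to -0.08); 1 of 38 genes were lower (5 lower over the list alone) (median -0.23, adjusted p = 0.000227, 0.215 estimated).

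As lists, sterol synthesis genes were higher under ethinyl estradiol than under estradiol benzoate (median 0.20, adjusted p = 0.023, 0.377 estimated). Oxidative phosphorylation genes were higher (median 0.19, adjusted p = 0.00296, 0.377 estimated). Mast cell genes were lower (median -0.33, adjusted p = 0.00655, 0.0665 estimated). Fibroblast genes were lower (median -0.27, adjusted p = 0.000227, 0.0661 estimated). Also lower were T and B lymphocyte (median -0.21, adjusted p = 0.0282, 0.377 estimated), macrophage and dendritic cell (median -0.16, adjusted p = 0.0419, 0.377 estimated) and intestinal epithelium genes (median -0.21, adjusted p = 0.027, 0.284 estimated). The pancreatic list was higher (median 2.08, adjusted p = 8.19e-05, 0.377 estimated), but not without ethinyl estradiol array 3 (median -0.14). The immediate early and heat shock list, of which Hspb1 is a member, was higher (median 0.22, adjusted p = 0.000296, 0.215 estimated). Score intervals included 0 for the sterol, oxidative phosphorylation, T and B lymphocyte, macrophage, intestinal and pancreatic lists. In all, 69 probes differed (41 higher and 28 lower), and with quantile normalisation 37 were higher and 45 lower. Under the array set block 65 differed, 61 of them among the 69, and Col1a1 did not pass. With single arrays left out the fit gave 23 (without estradiol benzoate array 1) to 77 (without ethinyl estradiol array 2), and leaving out raloxifene array 3 gave 259.

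Ethinyl estradiol and equilin, at the same dose, differed in smooth muscle and stress genes. Fmo2 was higher under ethinyl estradiol by 2.12 ± 0.32. Hspb1 was higher by 1.85 ± 0.21, at 7.80 ± 0.20 (SD, n = 3) against 5.95 ± 0.17 (SD, n = 3), with limma's adjusted p = 0.0012. Map1b, a microtubule protein, was higher by 1.82 ± 0.33, Pln by 1.32 ± 0.22, Cacna1h, a T-type calcium channel, by 1.19 ± 0.20, Lmod1 by 1.12 ± 0.17 and Zbp1, a nucleic acid sensor, by 1.18 ± 0.21. Arsi differed by -1.43 ± 0.27, Oxtr by -1.33 ± 0.26, Muc20 by -0.92 ± 0.18 and Pfkl, a phosphofructokinase whose other probe read 0.10, by -1.37 ± 0.27. The smooth muscle score differed by 0.57 (95% CI 0.36 to 0.78); 3 of 30 genes were higher (13 higher over the list alone) (median 0.52, adjusted p = 1.1e-08, 0.0164 estimated, or 0.133 without raloxifene array 3). The matrix score differed by 0.05 (95% CI -0.13 to 0.22), the cell cycle score by -0.05 (95% CI -0.23 to 0.13) and the fatty acid score by 0.12 (95% CI -0.22 to 0.46). These intervals include 0 and do not show that the compounds act alike.

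Channel and transporter genes were higher under ethinyl estradiol than under equilin (median 0.27, adjusted p = 0.0332, 0.405 estimated). Interferon response genes were higher (median 0.31, adjusted p = 0.00161, 0.153 estimated), as were immediate early and heat shock genes (median 0.56, adjusted p = 1.32e-06, 0.153 estimated). Adipocyte genes were lower (median -0.21, adjusted p = 0.00234, 0.153 estimated), as were fibroblast genes (median -0.20, adjusted p = 0.00939, 0.153 estimated). T and B lymphocyte (median -0.15, adjusted p = 0.00811, 0.388 estimated), lymphatic (median -0.10, adjusted p = 0.0484, 0.153 estimated) and intestinal genes (median -0.14, adjusted p = 0.0332, 0.249 estimated) were lower. Pancreatic genes were higher (median 1.98, adjusted p = 0.00614, 0.539 estimated) but lower without ethinyl estradiol array 3 (median -0.23, adjusted p = 0.0411). Score intervals included 0 for the adipocyte, fibroblast, T and B lymphocyte, intestinal and pancreatic lists. In all, 43 probes differed (36 higher and 7 lower), 33 of them also with the array set as a block, where Arsi, Pfkl and Oxtr did not pass. Here too the block alters the variance and not the changes. Leaving out 1 array gave 2 (without equilin array 1) to 35 (without ethinyl estradiol array 2), and leaving out raloxifene array 3 gave 301.

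Estradiol benzoate and equilin, at the same dose, differed in fatty acid and adipocyte genes as lists and at 0 single probes. The fatty acid score was lower under estradiol benzoate, with a difference of -0.55 (95% CI -0.89 to -0.21); 0 of 24 genes passed by limma (1 higher and 4 lower over the list alone, 1 higher and 7 lower unadjusted) (median -0.53, adjusted p = 3.09e-13, 0.0167 estimated). Adipocyte genes were lower (median -0.21, adjusted p = 2.61e-07, 0.0167 estimated). The matrix score differed by 0.24 (95% CI 0.06 to 0.41) (median 0.29, adjusted p = 0.00193, 0.116 estimated) and the cell cycle score by 0.21 (95% CI 0.03 to 0.39) (median 0.26, adjusted p = 0.017, 0.634 estimated). Oxidative phosphorylation genes passed as lower (median -0.05, adjusted p = 0.00272, 0.634 estimated), at a score difference of -0.05 (95% CI -0.43 to 0.34). The smooth muscle score differed by 0.14 (95% CI -0.06 to 0.35), and both intervals include 0. The genes named for this pair, which did not pass, were Me1 at -1.82 ± 0.28, Cbr1 at -1.67 ± 0.26, Mpc1 at -0.95 ± 0.17, Col1a1 at 1.14 ± 0.20, Cpz at 0.92 ± 0.20 and Hsd11b2 at 1.13 ± 0.25. By limma 0 probes passed, against 836 at an unadjusted p under 0.05, 6 with quantile normalisation and 4512 with array weights.

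Tamoxifen and raloxifene, both at 3 mg/kg, differed in cell cycle and smooth muscle lists. The cell cycle score differed by -0.29 (95% CI -0.46 to -0.12), lower under tamoxifen. Raloxifene array 3 (-0.002, others -0.29 and -0.22) widened this gap. Of 38 genes 0 passed (4 lower over the list alone, 13 lower unadjusted) (median -0.30, adjusted p = 3.59e-06, 0.272 estimated). The smooth muscle score differed by -0.35 (95% CI -0.55 to -0.15). Of 30 genes 0 passed, also over the list alone (5 lower unadjusted) (median -0.28, adjusted p = 0.000535, 0.272 estimated). Skeletal and cardiac muscle genes were lower under tamoxifen (median -0.25, adjusted p = 0.014, 0.605 estimated), and pancreatic genes higher (median 2.71, adjusted p = 0.00013, 0.698 estimated), with a score difference of 2.41 (95% CI -0.45 to 5.27). The matrix score differed by -0.02 (95% CI -0.18 to 0.15) and the fatty acid score by 0.27 (95% CI -0.04 to 0.59), and these 3 intervals include 0. A single probe passed, that of Armc5, higher under tamoxifen by 2.07 ± 0.30 (limma's adjusted p = 0.0391; its other probe 0.77), against 3291 probes at an unadjusted p under 0.05. It did not pass without raloxifene array 3 (adjusted p = 0.444) or with the array set as a block (adjusted p = 0.0574), which alters only the variance here.

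Estrogens at 0.15 mg/kg and SERMs at 3 mg/kg differ in dose as well as class, and all estrogen arrays lie in set A and all SERM arrays in set B. Scd was higher under estrogens by 1.90 ± 0.22 and was the only named gene to pass with the array set as a block, at 3.60 ± 0.33, a value that rests on the low reading of vehicle array 1. Without the block, Me1 was higher by 1.49 ± 0.16, Mest by 1.44 ± 0.20, Id2, an inhibitor of DNA binding, by 1.21 ± 0.34, Gapdhs by 1.05 ± 0.14, Slc25a16 by 0.99 ± 0.26 and the respiratory chain genes Atp5po and Ndufs1 by 0.55 ± 0.12 and 0.45 ± 0.11. Rpl34, a ribosomal protein gene, stood at -1.52 ± 0.23, Hdac2, a histone deacetylase, at -1.39 ± 0.33, Snupn at -1.38 ± 0.22, Fam234b at -1.42 ± 0.21 and Myh11, smooth muscle myosin, at -1.37 ± 0.19. Without raloxifene array 3, Id2 stood at 0.69 and Slc25a16 at 0.59. Other probes of Fam234b read 0.12 and 0.13, that of Slc25a16 0.05 and the brighter Myh11 probe 0.19. In the fatty acid list 8 of 24 genes rose (8 higher over the list alone) (median 0.39, adjusted p = 0.000299, 0.963 estimated), and the score differed by 0.40 (95% CI 0.18 to 0.61). In the oxidative phosphorylation list 6 of 48 genes rose and 5 fell (7 higher and 5 lower over the list alone) (median 0.17, adjusted p = 0.0487, 0.963 estimated; the score interval includes 0). The matrix score differed by 0.02 (95% CI -0.09 to 0.13). In all, 4585 probes differed (1356 higher and 3229 lower), 2410 of them with 1 symbol, and with no centring 1744 were higher and 2621 lower. With the array set as a block 19 differed, 2 of them among the 4585.

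Changes from vehicle were compared across all tested probes, which are not independent replicates. For pairs of estrogens the correlation was 0.592 for ethinyl estradiol and estradiol benzoate, 0.684 for ethinyl estradiol and equilin and 0.825 for estradiol benzoate and equilin, against simulated values without effects of 0.422, 0.422 and 0.426 from the shared vehicle arrays alone. The covariances were 0.112, 0.165 and 0.174 against simulated 0.0446, 0.0447 and 0.0452. With separate vehicle arrays for each compound the correlations were 0.322, 0.459 and 0.552. Tamoxifen and raloxifene gave 0.557 (simulated 0.448, covariance 0.0973 against 0.0441) and 0.267 with separate vehicle arrays. Estrogen and SERM pairs gave 0.0972 to 0.240 (simulated 0.419 to 0.459) and 0.116 to 0.332 with vehicle arrays of their own set. Separate ones gave -0.118 to 0.107 (single splits -0.432 to 0.329). The array set can add to estrogen pair correlations, as 3 of 4 vehicle arrays lie in set B. No value here separates it from the compounds.

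Of 12 genes fixed beforehand, 1 passed by its brightest probe under any single compound, Per2 under equilin. Others were Pgr, Adra1d, Agtr1a, Bmal1, Adipoq, the nitric oxide synthase gene Nos3 and the muscle genes Acta2 and Myh11. The rest were the estrogen receptor genes Esr1, Esr2 and Gper1. Acta2 (-1.17 to 0.69), Esr1 (-0.79 to 0.10) and Pgr (-0.54 to 0.34) read near the array median, a limit on their null results. Esr1 changed by 0.12 ± 0.21 under ethinyl estradiol, -0.08 ± 0.21 under estradiol benzoate, 0.02 ± 0.21 under equilin, -0.26 ± 0.19 under tamoxifen and 0.03 ± 0.21 under raloxifene. Pgr stood at 0.15 ± 0.16, 0.27 ± 0.16, 0.44 ± 0.16, 0.24 ± 0.15 and 0.27 ± 0.16 in the same order, and Nos3 at -0.24 ± 0.26, -0.48 ± 0.26, -0.21 ± 0.26, -0.23 ± 0.24 and -0.65 ± 0.26. For Myh11 under equilin a dimmer probe passed at -1.33 (adjusted p = 0.0185) where the brighter one read 0.03. In the comparison of estrogens with SERMs Agtr1a, an angiotensin receptor gene, stood at -0.82 ± 0.18 (adjusted p = 0.00369), Bmal1 at -0.51 ± 0.14 (adjusted p = 0.0169; another probe 0.20) and Adipoq at 0.48 ± 0.13 (adjusted p = 0.0144), and none of the 3 passed with the array set as a block.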

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

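The tests on the estrogen and SERM arrays and on the matrix genes were chosen after the results were seen; the counts over other splits of the arrays and the tests on raloxifene array 3 were planned, except that its tested-probe SD, 99th percentile and array weight were weighed after its dim-probe result was seen. In groups of 4 arrays, 186 values were tested for 1 array far from the other 3, and 12 passed a level that chance passes in about 1 in 20 groups.

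Hsd17b2 read -2.22 in vehicle array 1 against -1.47 to -1.35 in the other vehicle arrays, Inhbb 1.90 in vehicle array 2 against 1.37 to 1.44, Tekt3 3.83 in vehicle array 3 against 3.15 to 3.24, and Cpa3 2.26 in vehicle array 2 against 2.63 to 2.70. The circadian clock list scored 0.144 in vehicle array 4, the cell cycle list -0.144 in vehicle array 1 and the inflammatory and chemokine list 0.0639 in vehicle array 3. The median of the regularly spaced probes was 1.08 in vehicle array 1. Postn read 6.18 in tamoxifen array 3 against 5.63 to 5.71 in the other tamoxifen arrays, the sterol list scored 0.197 there and the immediate early and heat shock list 0.0608. The deposited median of tamoxifen array 4 was 1.01, at 1.015 before rounding, against 1.0111 to 1.0117 in the others.

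Estrogen and SERM arrays differed at 4585 probes, and 3 of the 4 vehicle arrays lie in the array set of the SERMs. Scaling of the arrays is argued against as the cause, since quantile normalisation gave 5130 probes, 1.12 times the count. The array set stays open: the change correlated at 0.348 with the difference of vehicle array 1 from the other vehicle arrays, but vehicle array 2 gave 0.454, and 1 array stands for the set. The class of compound stays open as well. With the array set as a block the median change of the called probes was 0.460 times as large (0.28 against 0.60), its standard error rose from 0.15 to 0.37 because only vehicle array 1 links the sets, and 85.3% of 4250 probes kept their direction.

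Raloxifene array 3 had the lowest mean correlation with the other arrays. Array quality stays open. The deviation of its dim probes from the other raloxifene arrays had an SD 1.13 times the highest in the other groups of 3, below the limit of 1.2 set beforehand as speaking against a fault. That limit misses a fault in bright probes, and other values go with one: over tested probes the SD was 1.03 against at most 0.75 in those groups, the 99th percentile of intensity was 183 against 66.4 to 104 in the other arrays, the array weight of 0.0701 was the lowest, and the dim-probe SD (0.71) the highest of the 20 arrays. Cells of another type stay open too: of 13 cell type lists 1, lymphatic and venous endothelium, passed the lower of a pair of limits set beforehand, lying above 98.9% of 10000 random lists, and 0 passed the higher. The pancreatic list lay above 0.14% of them. No biological explanation was tested, since the design separates this rat from the others of its group by nothing.

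Extracellular matrix genes were lower under all 5 compounds, although the list passed under ethinyl estradiol, equilin and tamoxifen and not under estradiol benzoate or raloxifene. A single low or high vehicle array is argued against, since 20 of 20 pairs of a compound and a vehicle array had a fitted list median below 0 (-0.60 to -0.19). Relative to the shift of all probes in each pair 19 were (range of all 20, -0.57 to 0.00), and estradiol benzoate, with the pair at 0.00, stays open. The array set is argued against as the only cause, since within set B the list fell under tamoxifen (median -0.31, camera p = 0.000297 with an estimated correlation, adjusted p = 0.00891). Fewer fibroblasts stay open: without the genes of the matrix list, the fitted fibroblast list median fell by at least 0.5 of the matrix median in 3 of the 5 compounds, and in 2 relative to the shift of all probes. A response of matrix genes to the compounds may remain a hypothesis, found and tested on the same data.

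Other splits of the same arrays were fitted to see whether chance alone gives such counts. For equilin 1 of 35 splits gave as many probes (real 906, highest other 745) and for tamoxifen 1 of 35 (55, 19). The share was 1 of 100 for the estrogen mean (640, 353), estrogens versus SERMs (4585, 1250) and any treatment (2171, 5). These lowest possible shares, uncorrected over the comparisons, do not exclude chance. Nor do 2 of 35 for ethinyl estradiol (295, 405) and estradiol benzoate (172, 345). The highest other count of these 3 estrogen comparisons came from the split that follows the array set. Counts with the set as a block are given above. Without the regularly spaced probes, the real and highest other counts were 164 and 3, 0 and 1, and 279 and 2. For raloxifene 3 of 35 splits (502, 867) and for tamoxifen versus raloxifene 6 of 35 splits (1, 13) leave chance open. So do 3 of 100 splits for the SERM mean (141, 635). Other splits calling more probes than the real one point to a structure among these arrays. The 10 splits of 6 arrays are too few for such a test: the real and highest other counts were 69 and 4 for ethinyl estradiol versus estradiol benzoate (1 of 10 splits), 43 and 0 for ethinyl estradiol versus equilin (1 of 10 splits) and 0 and 1 for estradiol benzoate versus equilin (10 of 10 splits).

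For list counts, 1 of 35 splits gave as many for ethinyl estradiol (real 12, highest other 10), which does not exclude chance. Chance is left open for estradiol benzoate (15 of 35 splits; 6, 13), equilin (10 of 35 splits; 9, 15), tamoxifen (13 of 35 splits; 7, 10), raloxifene (35 of 35 splits; 0, 6), tamoxifen versus raloxifene (4 of 35 splits; 4, 8), the estrogen mean (13 of 100 splits; 10, 14), the SERM mean (61 of 100 splits; 2, 9) and estrogens versus SERMs (61 of 100 splits; 2, 10). For estradiol benzoate the split by array set gave 6 lists, as many as the real one, and 12 passed with the set as a block. The splits are too few for ethinyl estradiol versus estradiol benzoate (1 of 10 splits; 13, 8), ethinyl estradiol versus equilin (1 of 10 splits; 10, 6) and estradiol benzoate versus equilin (3 of 10 splits; 5, 8).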

How the results depend on the processing

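The array set block and fits without outlying arrays or regularly spaced probes were chosen after seeing the results. Other alternatives were planned. A compound alone means its comparison with vehicle. Counts are of limma's or camera's adjusted p under 0.05. No passing named gene reversed in any alternative, which choosing many without overlapping groups largely fixed. Of 80 list results that passed, 4 turned with the array set as a block, all under ethinyl estradiol: the pancreatic list passed downward (median -1.73, adjusted p = 0.0285), and the interferon, immediate early and T and B lymphocyte lists did not pass. Without ethinyl estradiol array 3 the pancreatic list turned in all 3 of that compound's comparisons where it had passed (medians -1.80, -0.14 and -0.23). Without raloxifene array 3, with quantile normalisation and with no centring 0 turned by camera; the fitted median of the steroid list under estradiol benzoate went from -0.04 to 0.12 and 0.00 with those scalings. With no centring, a larger offset and no variance trend every count stayed within 1.5 times its value. Where a count moved further, its cause was not tested, except that fewer tested probes or arrays enter some fits by construction. Intensities near the offset limit the changes of dim genes.

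With quantile normalisation the probe counts were 22 for ethinyl estradiol versus equilin and 6 for estradiol benzoate versus equilin. There the list count was 1 for estrogens versus SERMs. With an offset of 0.01 times the median the probe counts were 191 for ethinyl estradiol and 0 for estradiol benzoate. With no filter on dim probes the probe counts were 111 for raloxifene and 22 for ethinyl estradiol versus equilin. There the list counts were 2 for estradiol benzoate and 1 for raloxifene. With the lowest 50% of probes left out the probe counts were 148 for ethinyl estradiol, 0 for estradiol benzoate, 536 for equilin, 2 for estradiol benzoate versus equilin and 323 for the estrogen mean. With array weights the probe counts were 506 for ethinyl estradiol, 485 for estradiol benzoate, 7565 for equilin, 449 for tamoxifen, 1031 for raloxifene, 431 for ethinyl estradiol versus estradiol benzoate, 1758 for ethinyl estradiol versus equilin, 4512 for estradiol benzoate versus equilin, 1581 for tamoxifen versus raloxifene, 1641 for the estrogen mean, 488 for the SERM mean, 10495 for estrogens versus SERMs and 7307 for any treatment. With only the compared groups in the fit the probe counts were 9 for ethinyl estradiol, 0 for estradiol benzoate, 130 for equilin, 34 for tamoxifen, 0 for raloxifene, 0 for ethinyl estradiol versus estradiol benzoate, 0 for ethinyl estradiol versus equilin, 1 for estradiol benzoate versus equilin, 0 for tamoxifen versus raloxifene and 12 for the SERM mean. With the correlation estimated per list the list counts were 3 for ethinyl estradiol, 0 for estradiol benzoate, 0 for equilin, 1 for tamoxifen, 0 for ethinyl estradiol versus estradiol benzoate, 1 for ethinyl estradiol versus equilin, 2 for estradiol benzoate versus equilin, 0 for tamoxifen versus raloxifene, 0 for the estrogen mean, 0 for the SERM mean and 0 for estrogens versus SERMs. With the mean over all probes of a gene the list count was 1 for raloxifene. Replicate numbers do not pair the rats: 46 pairs of arrays with the same number in different groups had a median correlation of 0.0239 against -0.00299 for different numbers. As a block they gave probe counts of 62 for ethinyl estradiol, 0 for estradiol benzoate, 365 for equilin, 46 for tamoxifen, 506 for raloxifene, 48 for ethinyl estradiol versus estradiol benzoate, 36 for ethinyl estradiol versus equilin, 2 for estradiol benzoate versus equilin, 1 for tamoxifen versus raloxifene, 421 for the estrogen mean, 148 for the SERM mean, 3751 for estrogens versus SERMs and 1493 for any treatment, and a list count of 1 for estrogens versus SERMs.

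With the array set as a block the probe counts were 134 for ethinyl estradiol, 100 for estradiol benzoate, 159 for equilin, 26 for tamoxifen, 5 for raloxifene, 0 for tamoxifen versus raloxifene, 167 for the estrogen mean, 33 for the SERM mean, 19 for estrogens versus SERMs and 169 for any treatment. There the list counts were 12 for estradiol benzoate, 4 for the SERM mean and 10 for estrogens versus SERMs. Without raloxifene array 3 the probe counts were 743 for ethinyl estradiol, 3069 for equilin, 166 for tamoxifen, 14 for raloxifene, 259 for ethinyl estradiol versus estradiol benzoate, 301 for ethinyl estradiol versus equilin, 2 for estradiol benzoate versus equilin, 0 for tamoxifen versus raloxifene, 1379 for the estrogen mean and 262 for the SERM mean. There the list counts were 2 for estradiol benzoate, 1 for raloxifene, 7 for tamoxifen versus raloxifene and 1 for estrogens versus SERMs. With the block and without raloxifene array 3 the probe counts were 320 for equilin, 95 for tamoxifen, 5 for raloxifene, 248 for ethinyl estradiol versus estradiol benzoate, 303 for ethinyl estradiol versus equilin, 2 for estradiol benzoate versus equilin, 0 for tamoxifen versus raloxifene, 272 for the estrogen mean, 83 for the SERM mean, 43 for estrogens versus SERMs and 434 for any treatment. There the list counts were 11 for estradiol benzoate, 3 for raloxifene, 7 for tamoxifen versus raloxifene, 5 for the SERM mean and 10 for estrogens versus SERMs. Without raloxifene array 3 and ethinyl estradiol array 3 the probe counts were 482 for ethinyl estradiol, 3930 for equilin, 233 for tamoxifen, 61 for raloxifene, 225 for ethinyl estradiol versus estradiol benzoate, 283 for ethinyl estradiol versus equilin, 5 for estradiol benzoate versus equilin, 0 for tamoxifen versus raloxifene, 1638 for the estrogen mean, 470 for the SERM mean and 3397 for any treatment. There the list counts were 1 for raloxifene and 16 for ethinyl estradiol versus equilin. Without the regularly spaced probes the probe counts were 164 for ethinyl estradiol, 0 for estradiol benzoate, 279 for equilin and 114 for the estrogen mean.

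Leaving out 1 array at a time moved these probe counts by over 1.5 times, with the arrays named. For ethinyl estradiol the range was 74 to 575, with 575, 116, 79 and 102 without vehicle 1, 2, 3 and 4 and 74, 176 and 120 without ethinyl estradiol 1, 2 and 3. For estradiol benzoate the range was 0 to 357, with 357, 1, 0 and 0 without vehicle 1, 2, 3 and 4 and 0, 0 and 1 without estradiol benzoate 1, 2 and 3. For equilin the range was 0 to 1429, with 1429, 64 and 167 without vehicle 2, 3 and 4 and 0 and 17 without equilin 2 and 3. For tamoxifen the range was 18 to 120, with 26 and 20 without vehicle 1 and 2 and 18, 19, 120 and 34 without tamoxifen 1, 2, 3 and 4. For raloxifene the range was 5 to 3774, with 5, 9, 23 and 1360 without vehicle 1, 2, 3 and 4 and 2326, 3774 and 14 without raloxifene 1, 2 and 3. For the estrogen mean the range was 298 to 670, with 298 and 384 without vehicle 3 and 4. For the SERM mean the range was 33 to 914, with 33, 42, 56 and 914 without vehicle 1, 2, 3 and 4, 56, 68, 470 and 72 without tamoxifen 1, 2, 3 and 4 and 829 and 262 without raloxifene 2 and 3. For any treatment the range was 996 to 3093, with 1347 and 1374 without estradiol benzoate 1 and 2, 1009 and 996 without equilin 2 and 3 and 1386 without tamoxifen 1. For ethinyl estradiol versus estradiol benzoate the range was 23 to 77, with 34 and 40 without ethinyl estradiol 1 and 3 and 23, 33 and 34 without estradiol benzoate 1, 2 and 3. For ethinyl estradiol versus equilin the range was 2 to 35, with 5 and 6 without ethinyl estradiol 1 and 3 and 2, 2 and 8 without equilin 1, 2 and 3. For tamoxifen versus raloxifene the range was 0 to 224, with 0, 0, 0 and 0 without tamoxifen 1, 2, 3 and 4 and 0, 224 and 0 without raloxifene 1, 2 and 3. The ranges with no such array were 3486 to 5171 for estrogens versus SERMs and 0 to 0 for estradiol benzoate versus equilin.

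List counts moved likewise. For estradiol benzoate the range was 1 to 10, with 3, 1 and 10 without vehicle 1, 2 and 3. For tamoxifen the range was 4 to 9, with 4 without vehicle 3. For raloxifene the range was 0 to 1, with 1 without vehicle 4 and 1 without raloxifene 3. For the estrogen mean the range was 5 to 11, with 5 without vehicle 2 and 6 without equilin 1. For the SERM mean the range was 1 to 4, with 4, 1 and 4 without vehicle 1, 2 and 4 and 1 and 1 without raloxifene 1 and 2. For ethinyl estradiol versus equilin the range was 6 to 13, with 6 and 6 without ethinyl estradiol 1 and 2. For estrogens versus SERMs the range was 1 to 2, with 1 without ethinyl estradiol 1, 1 without estradiol benzoate 1, 1 and 1 without equilin 1 and 2, 1 and 1 without tamoxifen 2 and 4 and 1 without raloxifene 3. For estradiol benzoate versus equilin the range was 3 to 7, with 3 without equilin 1. For tamoxifen versus raloxifene the range was 2 to 7, with 2 and 7 without raloxifene 1 and 3. The list ranges with no such array were 10 to 13 for ethinyl estradiol, 6 to 13 for equilin and 10 to 14 for ethinyl estradiol versus estradiol benzoate.

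Of 178 results that passed for genes chosen by the naming rule, 67 still passed with the array set as a block, 162 without raloxifene array 3, 155 without the regularly spaced probes, 143 with quantile normalisation and 74 with only the compared groups in the fit.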

Other observations

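Several vascular gene groups that the labels' question would bring to mind passed under none of the 5 compounds with all arrays. In the order ethinyl estradiol, estradiol benzoate, equilin, tamoxifen and raloxifene, endothelial genes had medians relative to the shift of all probes of -0.10, 0.08, 0.02, -0.03 and -0.17 (adjusted p 0.146 to 0.736), vasoactive receptor genes -0.00, 0.10, 0.05, 0.09 and 0.14 (0.114 to 0.887) and genes of nitric oxide, prostanoid and endothelin synthesis 0.05, -0.06, -0.10, 0.06 and 0.13 (0.239 to 0.995). Renin-angiotensin genes had medians of -0.17, -0.07, -0.29, -0.05 and -0.05 (0.169 to 0.976), circadian clock genes -0.04, -0.01, -0.20, 0.11 and -0.00 (0.0593 to 0.948), inflammatory and chemokine genes -0.13, 0.07, -0.00, 0.04 and -0.02 (0.229 to 0.839) and xenobiotic metabolism genes 0.08, -0.02, 0.09, 0.13 and -0.01 (0.0593 to 0.733). Fitted scores, which include that shift, had intervals below 0 for the vasoactive, nitric oxide, renin-angiotensin, clock and inflammatory groups under equilin, the nitric oxide, clock and xenobiotic groups under estradiol benzoate, renin-angiotensin under ethinyl estradiol and endothelial under raloxifene, and above 0 for xenobiotic under tamoxifen. A p that misses the threshold does not show that these groups did not change.

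Vehicle array 4 and tamoxifen array 3 were each other's closest arrays, with a correlation of 0.989. No further hypothesis was tested.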
